A study of Homo sapiens with 6 samples.

How the data were processed

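Total RNA of 6 SK-MES-1 cultures, 3 without exosomes and 3 with IPF fibroblast exosomes at 20 µg/ml for 72 h, was extracted with Trizol and made into libraries with a NEBNext Ultra RNA kit, per the labels' protocols, and sequenced on an Illumina NovaSeq instrument, per the labels. The aligner STAR and the genome build GRCh38 (hg38) are named by the submitters' processing notes. The program that counted reads, its annotation release and its use of strand are not given in the sources used here.

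One table of 15761 gene symbols held all values. Per the file headers, it has the authors' read counts per gene, which are whole numbers. It also has a normalised signal, which the authors made by dividing the counts by 1 size factor per library; these factors equal those DESeq2 computes from the counts. The authors' FPKM values, their log2 fold changes of exosome over control and their p-values, raw and adjusted, stand beside them in the deposited table; the tool behind that test is not stated, and 2712 adjusted p-values are exactly 1. The counts were used for every test here, and the signal and FPKM columns for none. Every row names a gene. Groups and replicate numbers came from the sample titles. Gene positions in the table start and end 1 base below GENCODE 29 for all 15490 genes with an Ensembl ID, so the table counts from 0, and positions are given here counted from 1 on GRCh38.

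Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, robust dispersion and quasi-likelihood fit with group as the only term), and p-values were adjusted by the Benjamini-Hochberg method over 12449 genes, with a threshold of 0.05. The standard error is the absolute log2 fold change over the square root of the F statistic. CPM values are counts scaled to the library total without TMM factors, so that a ratio of CPM means can differ slightly from a fitted fold. Library totals of 11346639 to 13334508 counts put 1 CPM at 11.3 to 13.3 reads, and intervals and levels cover these libraries only.

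The 34 gene lists and the rule for named genes were fixed before the data were examined. The rule takes MMP1 and F2R, the 10 largest rises and the 10 largest falls among protein-coding genes past the threshold with a mean of at least 1 CPM and all libraries of a group on one side of the other group, up to 4 members of each list with the smallest adjusted p, and members of a called list that moved against it. Some genes that the rule takes are not reported here. The lists cover signalling pathways, epithelial and mesenchymal states, proliferation, metabolism, stress, matrix, markers of other cell types and RNA quality. List symbols were matched to the table directly or through current gene names, 712 of 765 entries (the match of current names to rows without an Ensembl ID was repaired after first results had been seen, which brought CTGF into the TGF-beta list), and every list had at least 5 tested members. Lists were tested with camera from limma 3.58.1 on voom values with an inter-gene correlation of 0.01, adjusted over the lists. Rerunning with an estimated correlation and with the rotation test fry were alternatives.

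Libraries of a group were compared before averaging: the chi-square per gene was 2.29 to 15.6 within groups, so no pair agreed within sampling noise, and control library 3 lay farthest from its group. Transcript length and GC content were taken from the longest annotated transcript of each gene in GENCODE 29, and all 12449 tested genes had both. After a trend of the fold changes on GC content was seen, a correction was added: for each library, the log2 CPM minus the gene's mean was smoothed on GC and log2 length (loess, span 0.3), and the fitted trend entered edgeR as an offset, or was subtracted before camera. Lists were also compared with 10000 random lists whose members were drawn from the 100 genes nearest in GC, length and expression; that comparison treats genes as independent.

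The alternatives were RLE size factors, library totals only, no filter on low counts, at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a threshold of 0.01, a replicate block and leaving out each library in turn. On simulated counts without a trend, edgeR called 6 of 12249 unchanged genes and recovered 88% of genes changed 2-fold. With the GC and length trend of the real libraries added, it called 4081 unchanged genes (33.3%), while the corrected fit called 9 and recovered 94% of the 2-fold changes. The added trend came from the same fit that the correction uses, so the low number was largely set in advance. No other form of bias was simulated. Smaller changes were recovered less often: 72% (edgeR, no trend) and 78% (corrected, trend added) at 1.5-fold, and 24% in both at 1.25-fold.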

Results

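RNA sequencing was carried out on SK-MES-1 cells, an established line of human lung squamous carcinoma, cultured for 72 h with or without exosomes. Exosomes are small membrane vesicles that cells release. Those used here came from lung fibroblasts of idiopathic pulmonary fibrosis (IPF), a scarring disease of the lung, and were added at 20 µg/ml. Each group had 3 libraries, and the comparison asks what the vesicles do to the tumour cells' transcripts. The series title names senescent fibroblasts and the collagenase MMP1 carried by their exosomes. Total counts were 12721826, 11346639 and 12924251 in control libraries 1 to 3 and 13168627, 13038688 and 13334508 in exosome libraries 1 to 3, with 14294 to 14540 genes detected per library. The labels do not say how separate the cultures of a group were, so p-values measure the spread between these 3 and 3 samples, which may be technical.

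With exosomes, the serpin genes SERPINB3 and SERPINB4, which encode the squamous cell carcinoma antigens, rose 10.4-fold and 10.1-fold. The acute-phase and inflammatory genes S100A9, LRG1 and FGG (fibrinogen gamma chain) rose 6.33-fold, 4.56-fold and 5.21-fold. ANKRD1, a target of the YAP-TEAD transcription complex, fell 6.77-fold. As groups, NF-kB and TNF targets and DNA replication genes were higher, while TGF-beta targets, YAP-TEAD targets and mesenchymal genes were lower. With an estimated correlation between genes these lists did not pass (adjusted p = 0.166 for 4 of them and 0.276 for mesenchymal genes, each with an estimated correlation). Their estimated correlations were low: -0.012 (DNA replication), 0.020 (TGF-beta), 0.024 (NF-kB), 0.036 (YAP-TEAD) and 0.060 (mesenchymal), against camera's preset 0.01. For DNA replication genes the estimate lay below the preset, so members moving together cannot be what raised their p-value. For the other lists it need not be, and the cause was not tested. MMP1 transcripts of the tumour cells did not pass the test, which does not measure MMP1 protein carried by the exosomes.

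SERPINB3 went from 2.13 ± 0.774 CPM (read count scaled to the library total; mean ± SD, n = 3 here and below) in control to 23.8 ± 0.954 CPM with exosomes, and its neighbour SERPINB4 from 4.59 ± 0.871 to 49.0 ± 7.38 CPM. Their log2 fold changes were 3.38 ± 0.19 (SE; edgeR quasi-likelihood test, adjusted p = 2.62e-11) and 3.34 ± 0.15 (adjusted p = 5.44e-13). SERPINB3 lies on chromosome 18 from 63655197 to 63661963 and SERPINB4 from 63637259 to 63644298 (GRCh38), and their near-identical sequences leave the share of reads given to each uncertain. LRG1, on chromosome 19 from 4536409 to 4540474, rose from 28.1 ± 0.143 to 136 ± 10.8 CPM (log2 fold change 2.19 ± 0.088, adjusted p = 1e-13). S100A9, on chromosome 1 from 153357854 to 153361027, rose from 6.18 ± 1.58 to 41.5 ± 5.42 CPM. The other genes among the 10 largest rises were IL1RL1, the interleukin-33 receptor (7.39-fold), SFTPB, surfactant protein B (6.42-fold), ADAMTS14 (4.75-fold), PDZK1IP1 (4.61-fold) and HYPK (4.48-fold), with FGG already given. Levels of IL1RL1, SFTPB and PDZK1IP1 in control were below 1 CPM, at 0.485 ± 0.127, 0.494 ± 0.238 and 0.572 ± 0.161 CPM, so their folds rest on few reads.

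ANKRD1, on chromosome 10 from 90912096 to 90921276, fell from 31.8 ± 1.85 to 4.96 ± 0.0859 CPM (log2 fold change -2.76 ± 0.13, adjusted p = 1.36e-12). The placental alkaline phosphatases ALPP and ALPG fell 5.03-fold and 4.37-fold, the smooth muscle actin ACTG2 5.45-fold, and IGFBP5, a binding protein of insulin-like growth factors, 4.14-fold. LBH fell 4.11-fold, the hair keratin KRT81 4.06-fold, the pregnancy glycoprotein PSG5 3.86-fold and the phosphatase subunit PPP2R2C 3.80-fold. With exosomes, ACTG2, ALPG and PPP2R2C were below 1 CPM, at 0.406 ± 0.160, 0.581 ± 0.382 and 0.553 ± 0.430 CPM, so their folds rest on few reads. The fall of ALPG was larger without exosome library 1 (log2 fold change -2.73 against -2.13), and that of PPP2R2C without exosome library 3 (-2.78 against -1.92). ALPP and ALPG, KRT81 and PSG5 have close relatives that can share reads. In the annotation, HYPK overlaps SERF2, IL1RL1 overlaps IL18R1, SERPINB3 overlaps SERPINB11, KRT81 overlaps KRT86, and LRG1 overlaps an unnamed coding gene. MMP1, F2R, ALPP, IGFBP5 and PSG5 overlap a pseudogene or antisense gene, and the use of strand in the counting is not given in the sources used here. The 10 genes with the largest rises and 10 with the largest falls all stayed past the threshold in the same direction with the GC and length trend described next removed.

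**Figure D1:**
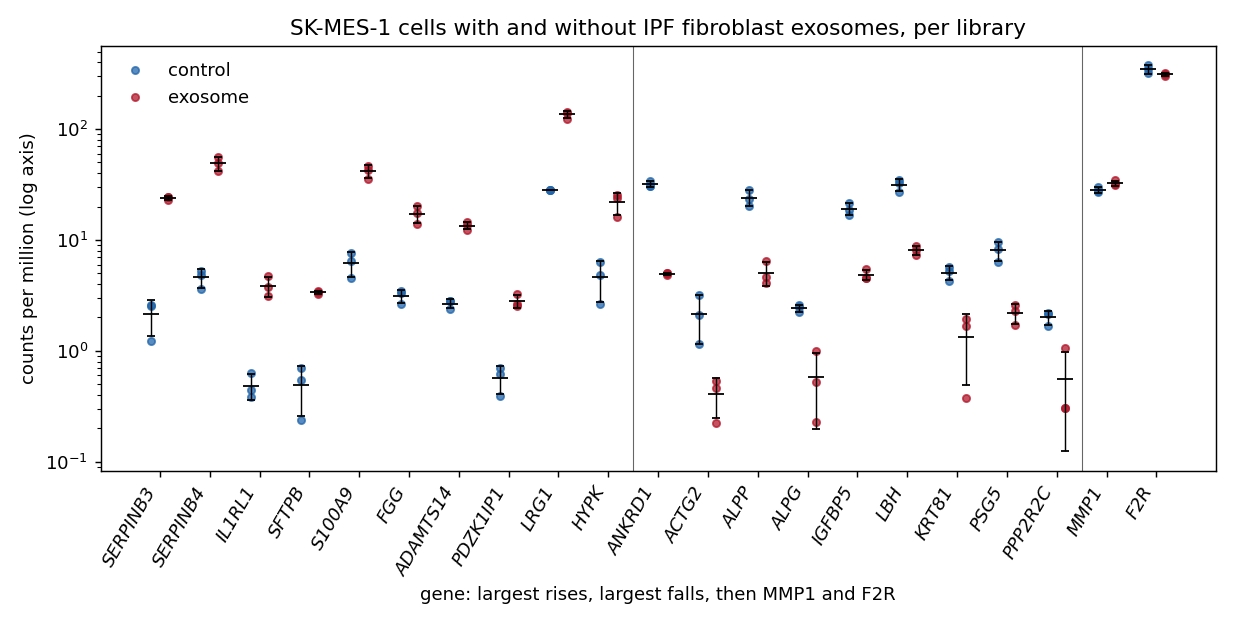
CPM (log axis) of the 10 genes with the largest rise, the genes named here among the 10 with the largest fall, and MMP1 and F2R, in each of 3 control (blue) and 3 exosome (red) libraries; black dashes and bars are the mean and SD. All 3 exosome libraries lie on one side of all 3 control libraries for all genes drawn except F2R; MMP1 goes from 28.1 to 32.4 CPM.

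Of 12449 genes tested, 3190 were higher and 3244 lower with exosomes at an adjusted p under 0.05, and 363 and 161 of these differed by at least 2-fold. In 59.5% of the tested genes all exosome libraries lay on one side of all control libraries, where chance gives 10%. Scaled by library totals alone, 3811 genes were higher and 2495 lower, so that 60.4% of calls were higher against 49.6%. The fold changes followed transcript composition: across genes, which are not independent replicates, their Spearman correlation was 0.62 with GC content and -0.39 with transcript length. From the lowest to the highest of 10 bins of GC content, the median log2 fold change went from -0.39 to 0.49. Genes called higher had a median GC content of 57.8% and genes called lower 41.3%. Per 10 percentage points of GC, the log2 level of a gene relative to its mean over the libraries changed by -0.137 ± 0.036 in control and 0.137 ± 0.079 in exosome libraries (mean ± SD, n = 3). With this trend and that of length removed within each library, a correction chosen after seeing the data, 2153 genes were higher and 2211 lower. Of those, 1505 and 1471 were also called in the same direction without it. The correction ended 3359 calls, and turned 59 from higher to lower and 40 from lower to higher. With the correction, 120 genes were higher and 165 lower by at least 2-fold. Of the 363 and 161 genes past 2-fold without it, 282 and 146 kept their call in the same direction, at a fold of any size. Values with the trend removed are called corrected below, where a pair of values in parentheses after a gene is its log2 fold change and the corrected one. Control library 3 differed more from control libraries 1 and 2 (chi-square per gene 15.6 and 11.7) than these did from each other (2.29), and exosome library 3 more from exosome libraries 1 and 2 (9.34 and 7.15) than these did (3.11). Without control library 3, 3072 genes were higher and 2933 lower, and without exosome library 3, 3234 and 3375.

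**Figure D2:**
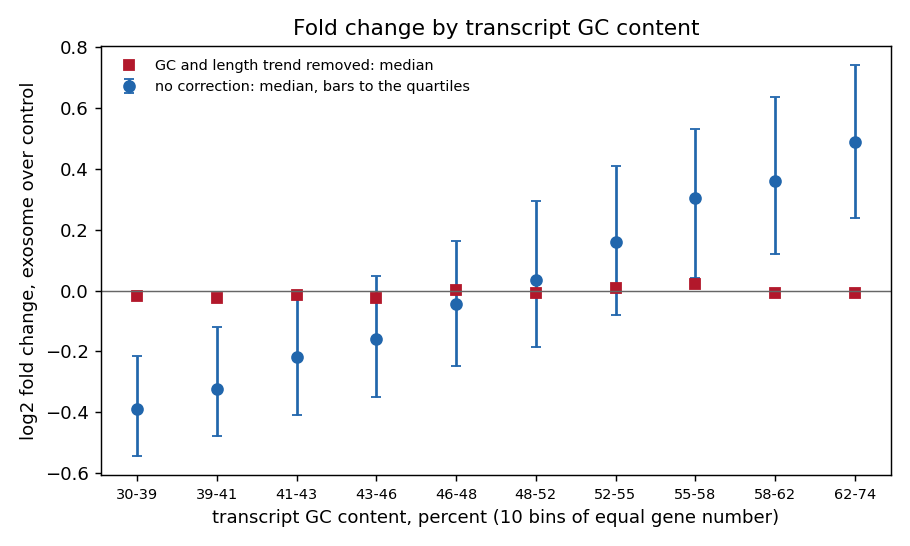
Log2 fold change (exosome over control) of the 12449 tested genes in 10 bins of transcript GC content in percent; blue points are medians with bars to the quartiles, and red squares are medians with the trend removed. The uncorrected medians go from -0.39 in the lowest bin to 0.49 in the highest.

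MMP1, on chromosome 11 from 102789920 to 102798160, had 28.1 ± 1.68 CPM in control and 32.4 ± 1.76 CPM with exosomes. Its log2 fold change of 0.12 ± 0.10 had a 95% confidence interval of -0.10 to 0.34 and did not pass the test (adjusted p = 0.347; corrected 0.15, adjusted p = 0.229). Transcript levels show neither MMP1 protein delivered by exosomes, nor cleavage of its receptors, nor the activity of signalling proteins. No group received other vesicles or exosomes without MMP1. F2R, on chromosome 5 from 76716043 to 76735781, encodes PAR1, a receptor that MMP1 can cleave. It had 346 ± 29.5 CPM in control and 312 ± 10.8 CPM with exosomes, a log2 fold change of -0.23 ± 0.078 (adjusted p = 0.0171). That call ended with the correction (log2 fold change -0.10 ± 0.058, adjusted p = 0.178), with scaling by library totals (adjusted p = 0.114), and without control library 2 or 3 or exosome library 1 or 2 (adjusted p = 0.0656 to 0.0767). Over the alternatives its adjusted p was 0.00127 to 0.178. Among 20 tested genes of protease-activated receptors, thrombin and matrix metalloproteinases, 2 were higher and 6 lower (camera adjusted p = 0.343). Its lower members included F3, tissue factor, at 56.8 ± 4.85 and 29.3 ± 2.84 CPM (log2 fold change -1.04, corrected -0.99), and the protease inhibitor TIMP2 (-0.60, corrected -0.77). BSG, which encodes basigin, was higher by 0.39, but its corrected value of -0.089 did not pass (adjusted p = 0.230). With the correction the list was lower (1 higher, 8 lower, adjusted p = 0.0122, or adjusted p = 0.197 with an estimated correlation). Its uncorrected median lay only at percentile 36.66 of random lists matched on GC, length and expression, so the 2 ways of allowing for the trend differ here. Of 29 PI3K-AKT-mTOR components, 11 were higher and 10 lower, or 11 and 12 adjusted over the list alone, and the list did not pass (adjusted p = 0.684; corrected 5 and 8, adjusted p = 0.755). The catalytic subunit PIK3CB (log2 fold change -0.63, corrected -0.28) and the phosphatase INPP4B (-0.83, corrected -0.35) fell, while the adaptor IRS1 (0.53, corrected 0.65) and the mTORC1 inhibitor AKT1S1 (0.72, corrected 0.38) rose.

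Targets of TGF-beta, a cytokine that drives matrix production, were lower with exosomes: of 19 tested, 13 fell and 1 rose (median log2 fold change -0.94, camera adjusted p = 1.13e-05 with its preset correlation of 0.01, or adjusted p = 0.166 with an estimated correlation between genes). TGFB2 fell from 160 ± 2.82 to 64.2 ± 4.33 CPM (-1.39, corrected -1.06), CTGF from 44.1 ± 1.72 to 16.4 ± 0.693 CPM (-1.51, corrected -1.69) and THBS1 from 515 ± 41.7 to 260 ± 21.1 CPM (-1.06, corrected -0.84). TGFB1, which like TGFB2 encodes a TGF-beta ligand, was the member that rose (log2 fold change 0.25, adjusted p = 0.0262). TGFB1 was lower after correction (-0.22, adjusted p = 0.0323) and not called without control library 2 or 3 or exosome library 1 or 2 (adjusted p = 0.0642 to 0.0865). Corrected, 14 members were lower and 0 higher in edgeR's test (median -0.68, adjusted p = 1.98e-11, or adjusted p = 0.0611 with an estimated correlation). Of 17 YAP-TEAD targets, 13 fell and 1 rose (median -0.56, adjusted p = 1.40e-05, or adjusted p = 0.166 with an estimated correlation). Corrected, 12 were lower and 1 higher (median -0.26, adjusted p = 2.12e-07, or adjusted p = 0.0990 with an estimated correlation). ANKRD1, CTGF, F3 and CRIM1 (-0.72, corrected -0.59) were the members with the smallest adjusted p, and all of them fell. WWC1, which encodes the Hippo pathway scaffold KIBRA, rose by 0.41 (corrected 0.37). CTGF is in both lists. Other lists share members as well: F3 is in the YAP-TEAD and protease-activated receptor lists, and TAGLN and TGFBI in the TGF-beta and mesenchymal lists. THBS1 is in the TGF-beta and matrix lists, FN1 in the mesenchymal and matrix lists, and ITGAV in the mesenchymal and integrin lists. The lower lists are therefore not independent of each other.

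Mesenchymal genes of the epithelial-mesenchymal transition were lower, with 11 of 17 lower and 2 higher (median -0.41, adjusted p = 0.00115, or adjusted p = 0.276 with an estimated correlation; corrected 11 lower and 0 higher in edgeR's test, adjusted p = 5.85e-05, or adjusted p = 0.190 with an estimated correlation). Fibronectin (FN1) fell from 355 ± 15.8 to 224 ± 7.79 CPM (-0.74, corrected -0.39), ITGAV from 316 ± 21.01 to 189 ± 16.8 CPM (-0.82, corrected -0.41) and TAGLN from 11.6 ± 2.06 to 4.53 ± 0.522 CPM (-1.44, corrected -1.73). TGFBI changed by -0.56 (corrected -0.59). The exceptions were SNAI1, a transcription factor that represses E-cadherin (0.52, corrected 0.10 with adjusted p = 0.504), and ITGA5 (0.21, corrected 0.087 with adjusted p = 0.209). ITGA5 lost its call without control library 1 or 2 or exosome library 1 (adjusted p = 0.0616 to 0.0905). Of 20 integrins and adhesion receptors, 11 were lower, or 12 adjusted over the list alone, and 3 higher (adjusted p = 0.0472, or adjusted p = 0.400 with an estimated correlation; corrected 10 lower and 2 higher, adjusted p = 0.000914, or adjusted p = 0.197 with an estimated correlation). L1CAM (-1.25, corrected -1.51) and ALCAM (-0.84, corrected -0.53) fell, and ICAM1 (1.14, corrected 0.86) rose. ITGB4 and ITGA5 were the other members that rose, ITGB4 by 0.34 (corrected 0.0062, adjusted p = 0.948). That list missed the threshold without control library 1 (adjusted p = 0.0511) or exosome library 3 (adjusted p = 0.0639). Of 24 collagens and matrix glycoproteins, 10 were lower and 6 higher (adjusted p = 0.0650). Corrected, 15 were lower and 1 higher, and the list passed (adjusted p = 5.60e-06, or adjusted p = 0.123 with an estimated correlation). Its uncorrected median lay at percentile 7.35 of random lists matched on GC, length and expression, which is not extreme. COL1A2 fell from 40.8 ± 3.65 to 13.6 ± 1.84 CPM (-1.67, corrected -1.38), COL1A1 from 60.2 ± 3.09 to 30.6 ± 2.55 CPM (-1.06, corrected -1.31) and COL12A1 from 379 ± 35.9 to 197 ± 3.11 CPM (-1.03, corrected -0.76). This list passed without correction when control library 2 or 3 or exosome library 1 was left out (adjusted p = 0.0420, 0.0466 and 0.0219).

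NF-kB and TNF targets were higher: 12 of 16 rose and 0 fell in edgeR's test (median 0.50, camera adjusted p = 0.000256, or adjusted p = 0.166 with an estimated correlation). Corrected, 8 rose (adjusted p = 0.000914, or adjusted p = 0.119 with an estimated correlation). ICAM1 rose from 37.4 ± 2.93 to 87.2 ± 2.82 CPM, IRF1 from 17.96 ± 0.548 to 35.6 ± 3.43 CPM (0.90, corrected 0.84) and TNFAIP2 from 375 ± 17.6 to 625 ± 73.7 CPM (0.65, corrected 0.31). TNFAIP3, which encodes A20, an inhibitor of NF-kB signalling, rose from 5.95 ± 0.264 to 14.6 ± 2.15 CPM (1.21, corrected 1.22). Of 18 senescence-associated secretory factors, 7 were higher and 1 lower (adjusted p = 0.0573; corrected 8 and 2, adjusted p = 0.0420, or adjusted p = 0.195 with an estimated correlation). IGFBP6 (1.37, corrected 0.71), VEGFA (0.93, corrected 0.97) and IGFBP3 (0.60, corrected 0.48) rose, and IGFBP5 fell. That list passed without control library 2 (adjusted p = 0.0491) and without exosome library 1 or 2 (adjusted p = 0.0412 and 0.04995). Of 31 interferon-stimulated genes, 12 were higher and 4 lower (adjusted p = 0.0778). Corrected, 12 were higher and 1 lower (adjusted p = 0.00842, or adjusted p = 0.195 with an estimated correlation), and without exosome library 1 the uncorrected list passed (adjusted p = 0.0443). IFIT2 (0.57, corrected 0.74) and BST2 (0.73, corrected 0.23) rose and SAMD9 (-0.79, corrected -0.33) fell, while the rise of ISG15 (0.55) was not seen after correction (-0.16, adjusted p = 0.168). Of 25 ERK output and AP-1 genes, 11 were higher and 5 lower (adjusted p = 0.162; corrected 8 and 6). JUNB rose from 87.8 ± 1.24 to 245 ± 38.7 CPM (log2 fold change 1.40, corrected 0.80), and IER2 (0.74, corrected 0.33), MYC (0.57, corrected 0.32) and JUN (0.55, corrected 0.30) rose as well.

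DNA replication and S phase genes were higher: 18 of 29 rose and 0 fell in edgeR's test (median 0.37, camera adjusted p = 1.13e-05, or adjusted p = 0.166 with an estimated correlation). Corrected, 22 rose (adjusted p = 8.09e-08, or adjusted p = 0.0611 with an estimated correlation). CHAF1A, a histone chaperone subunit, rose from 44.8 ± 0.553 to 83.4 ± 9.66 CPM (0.81, corrected 0.52), the flap endonuclease FEN1 from 47.9 ± 1.71 to 83.4 ± 3.96 CPM (0.72, corrected 0.47), and the licensing factors CDT1 and MCM7 by 0.97 and 0.57 (corrected 0.49 and 0.26). Of 29 G2-M and mitosis genes, 12 were higher and 7 lower (adjusted p = 0.227). Corrected, 20 were higher and 2 lower (adjusted p = 2.97e-06, or adjusted p = 0.136 with an estimated correlation); the median GC content of this list was 42.6%. AURKB (1.06, corrected 0.66), CDC20 (0.72, corrected 0.32), CENPA (0.89, corrected 0.73) and KIF20A (0.64, corrected 0.61) rose. Of 19 p53 targets and cell-cycle inhibitors, 6 were higher and 7 lower (adjusted p = 0.790; corrected 3 and 3). BAX (1.14, corrected 0.65), GADD45A (0.98, corrected 0.72) and GADD45B (0.83, corrected 0.39) rose and CDKN2B, which encodes the inhibitor p15, fell (-0.85, corrected -0.72).

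Of 29 ribosomal protein genes, 21 were higher and 1 lower (median 0.51, adjusted p = 4.05e-07, or adjusted p = 0.400 with an estimated correlation). Corrected, 16 were higher and 1 lower (median 0.27, adjusted p = 9.90e-07, or adjusted p = 0.195 with an estimated correlation). RPL18 rose from 260 ± 12.4 to 456 ± 36.8 CPM (0.73, corrected 0.51), RPL13 by 0.80 (corrected 0.61), RPS12 by 0.76 (corrected 0.41) and RPS2 by 0.66 (corrected 0.25), and RPS3A fell (-0.26, corrected -0.24). RPS3A lost its call when scaled by library totals (adjusted p = 0.0822) and without control library 2 (adjusted p = 0.0883) or exosome library 1 (adjusted p = 0.138). These genes have many pseudogenes that can take a share of their reads. Of 22 nuclear genes of oxidative phosphorylation, 12 rose, or 13 adjusted over the list alone, and 0 fell in edgeR's test (median 0.37, camera adjusted p = 0.000256, or adjusted p = 0.400 with an estimated correlation). Corrected, 11 were higher and 2 lower (median 0.25, adjusted p = 0.00470, or adjusted p = 0.197 with an estimated correlation). NDUFA2 (0.997, corrected 0.60), COX4I1 (0.61, corrected 0.63) and ATP5MC1 (0.61, corrected 0.53) rose, while CYC1 went from 0.54 to a corrected -0.048 (adjusted p = 0.637). The 13 genes encoded on mitochondrial DNA went the other way: 7 fell and 0 rose (median -0.43, adjusted p = 0.000892, or adjusted p = 0.400 with an estimated correlation). Corrected, 10 fell (adjusted p = 2.08e-07, or adjusted p = 0.195 with an estimated correlation). MT-ND4L (-1.17, corrected -1.52), MT-ND6 (-1.02, corrected -1.25), MT-ND5 (-0.64, corrected -0.67) and MT-ATP6 (-0.52, corrected -0.72) had the smallest adjusted p of the list. Mitochondrially encoded genes took 9.18%, 8.56% and 6.45% of counts in the control libraries and 6.04%, 5.98% and 7.003% in the exosome libraries, so the groups overlapped in this share. Of 19 glycolysis genes, 9 were higher and 1 lower (adjusted p = 0.0495, or adjusted p = 0.400 with an estimated correlation), and the call ended with the correction (5 higher, 5 lower, adjusted p = 0.755) and without control library 1 or 2 or exosome library 3 (adjusted p = 0.0564, 0.0702 and 0.0514). SLC16A3, a lactate exporter (0.89, corrected 0.54), ENO2 (0.73, corrected 0.47) and TPI1 (0.60, corrected 0.21) rose, PFKL went from 0.44 to a corrected 0.086 (adjusted p = 0.352), and LDHA was the member that fell (-0.21, corrected -0.15 with adjusted p = 0.0573). LDHA lost its call when scaled by library totals (adjusted p = 0.158) and without control library 1 or 2 or exosome library 1 or 2 (adjusted p = 0.0509 to 0.115). Of 22 hypoxia targets, 9 were higher and 5 lower (adjusted p = 0.293; corrected 7 and 4). CA9 (1.12, corrected 0.64), VEGFA and SLC2A3 (0.50, corrected 0.61) rose and LOX (-0.52, corrected -0.19) fell.

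**Figure D3:**
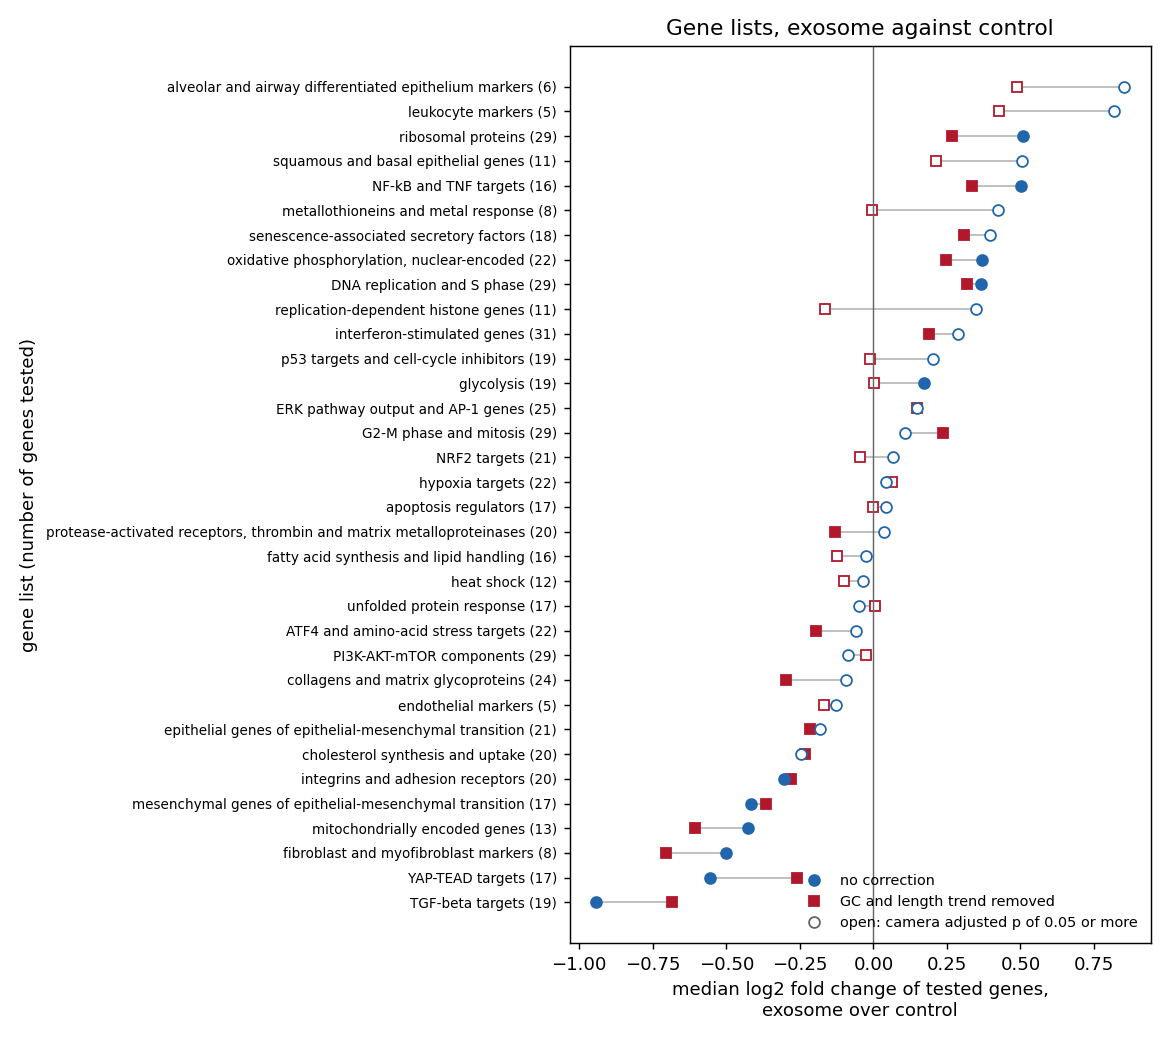
Median log2 fold change (exosome over control) of the tested genes of each of 34 gene lists, without correction (blue circles) and with the GC and length trend removed (red squares); filled symbols have a camera adjusted p under 0.05. TGF-beta targets are lowest without correction, at -0.94 (corrected -0.68), and ribosomal protein genes go from 0.51 to 0.27.

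Of 20 genes of cholesterol synthesis and uptake, 10 were lower and 4 higher, or 12 and 5 adjusted over the list alone (adjusted p = 0.0778). Corrected, 10 were lower and 1 higher, and the list passed (adjusted p = 0.00203, or adjusted p = 0.197 with an estimated correlation). Uncorrected, it passed without control library 2 or exosome library 1 or 2 (adjusted p = 0.0429, 0.0359 and 0.0408). INSIG1 (-0.81, corrected -0.77), STARD4 (-1.06, corrected -0.63), MSMO1 (-0.67, corrected -0.49) and HMGCS1 (-0.55, corrected -0.31) fell. Of 16 genes of fatty acid synthesis and lipid handling, 4 were higher and 6 lower (adjusted p = 0.506; corrected 6 and 8). SCD, the stearoyl-CoA desaturase, fell from 1696 ± 147 to 694 ± 24.4 CPM (-1.37, corrected -1.26), ACSL4 (-0.63, corrected -0.25) and ACSL3 (-0.52, corrected -0.14) fell, and the lipid droplet gene PLIN2 rose from 68.1 ± 0.373 to 127 ± 3.84 CPM (0.81, corrected 0.68). Of 22 ATF4 and amino-acid stress targets, 5 were higher and 7 lower (adjusted p = 0.370; corrected 4 and 9, adjusted p = 0.00489, or adjusted p = 0.197 with an estimated correlation). Asparagine synthetase (ASNS) fell from 129 ± 14.1 to 70.2 ± 3.70 CPM (-0.96, corrected -1.01), the cystine transporter SLC7A11 from 80.5 ± 10.1 to 38.7 ± 4.13 CPM (-1.14, corrected -0.60), ALDH1L2 by 1.34 on the log2 scale (corrected -1.02) and PSAT1 from 152 ± 6.81 to 97.4 ± 7.70 CPM (-0.73, corrected -0.65).

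The other stress lists did not pass. Of 17 genes of the unfolded protein response, 8 were higher and 4 lower (adjusted p = 0.625; corrected 5 and 2), with CANX at 0.51 (corrected 0.75) and DNAJC3 at -0.75 (corrected -0.42). Its members SDF2L1 (0.76, corrected 0.0070 with adjusted p = 0.971) and SEL1L (-0.52, corrected -0.12 with adjusted p = 0.0960) lost their calls with the correction. Of 21 NRF2 targets, 4 were higher and 4 lower, or 4 and 3 adjusted over the list alone (adjusted p = 0.684; corrected 4 and 5), with TKT at 0.47 (corrected 0.38), AKR1C3 at -0.81 (corrected -0.75) and HMOX1 at 0.53 (corrected 0.12, adjusted p = 0.186). Of 12 heat shock genes, 2 were higher and 4 lower (adjusted p = 0.429; corrected 0 and 5), with HSPH1 at -0.58 (corrected -0.26), DNAJB4 at -0.79 (corrected -0.44), HSP90AA1 at -0.43 (corrected -0.34) and BAG3 at 0.44 (corrected 0.12, adjusted p = 0.237). Of 8 metallothionein and metal response genes, 4 were higher and 1 lower (adjusted p = 0.326), and the correction left 1 higher and 2 lower and turned the median from 0.42 to -0.0053, with MT2A at 0.88 (corrected 0.45) and SLC30A1 at -0.53 (corrected -0.15, adjusted p = 0.0662). MT1A (0.97, corrected 0.50 with adjusted p = 0.191) lost its call with the correction and without exosome library 2 (adjusted p = 0.0602). Of 17 apoptosis regulators, 4 were higher and 4 lower (adjusted p = 0.820; corrected 4 and 2), with CASP8 at 0.35 (corrected 0.49) and XIAP at -0.50 (corrected -0.075, adjusted p = 0.354).

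Of 21 epithelial genes of the epithelial-mesenchymal transition, 5 were higher and 7 lower, or 5 and 8 adjusted over the list alone (adjusted p = 0.429; corrected 3 and 9, adjusted p = 0.0252, or adjusted p = 0.195 with an estimated correlation). CDH1, which encodes E-cadherin, fell from 51.5 ± 2.63 to 20.7 ± 0.927 CPM (-1.39, corrected -1.35), and the claudins moved apart, with CLDN1 at -1.78 (corrected -1.58), CLDN4 at 0.72 (corrected 0.48) and CLDN7 at 1.14 (corrected 0.69). Of 11 squamous and basal epithelial genes, 5 were higher and 2 lower (adjusted p = 0.218; corrected 4 and 3). S100A9, KRT15 (1.15, corrected 0.99) and SFN (0.94, corrected 0.35) rose and KRT17 (-1.71, corrected -2.11) fell. Of 11 replication-dependent histone genes, a list taken as a measure of RNA quality, 4 were higher and 1 lower (adjusted p = 0.429). With the correction 2 were higher and 4 lower, and the median turned from 0.35 to -0.17. HIST2H2BE was at 0.44 (corrected 0.36), HIST1H4H at -0.58 (corrected -0.55) and HIST1H2BD at 0.37 (corrected 0.11, adjusted p = 0.338), while HIST1H1C turned from 0.36 to -0.23 with the correction (adjusted p = 0.0423). HIST1H1C and HIST1H2BD lost their calls without exosome library 2 (adjusted p = 0.0774 and 0.0592).

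Markers of other cell types were measured as a check on the cultures. Of 8 fibroblast and myofibroblast markers tested, 5 were lower and 0 higher (median -0.50, adjusted p = 0.00912, or adjusted p = 0.237 with an estimated correlation; corrected 7 lower, adjusted p = 5.85e-05, or adjusted p = 0.0990 with an estimated correlation). The lower ones included COL1A1, COL1A2, LOX and COL6A3 (-1.30, corrected -1.25), and 6 of the 8 are also in another list. Of 5 endothelial markers tested with edgeR, 0 were called; CDH5 (0.21 ± 0.16), PECAM1 (-0.26 ± 0.31), KDR (-0.30 ± 0.37) and ROBO4 (-0.13 ± 0.49) had adjusted p-values of 0.287 to 0.849. With the correction 0 were called as well. Of 5 leukocyte markers, 4 were higher and 1 lower (adjusted p = 0.187; corrected 1 and 1). CD14, which encodes a receptor for bacterial lipopolysaccharide, rose from 23.0 ± 0.276 to 69.9 ± 8.19 CPM (1.52, corrected 1.12), and CSF1R fell (-0.87, corrected -1.11), while CORO1A (1.16, corrected 0.71 with adjusted p = 0.0652) lost its call with the correction. Of 6 alveolar and airway epithelium markers, 4 were higher and 1 lower (adjusted p = 0.227; corrected 3 and 2). SFTPB, NAPSA (1.44, corrected 1.20) and FOXJ1 (1.30, corrected 0.76) rose from 0.494, 1.99 and 3.79 CPM to 3.36, 5.77 and 9.88 CPM, and CAV1 fell (-0.73, corrected -0.69).

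Of the 34 lists, 5 were higher and 6 lower with camera's preset correlation. With an estimated correlation 0 passed, 6 had an unadjusted p under 0.05, and the rotation test fry, which does not compare a list with other genes, called 27. The counts adjusted over the list alone equalled those over all genes in 28 lists and differed in 6, each given above. The median and the tested direction differed in sign for the protease-activated receptor list (median 0.036, mean -0.11, lower), and the median and mean did so for fatty acid synthesis (-0.024 and 0.058, lower) and the unfolded protein response (-0.049 and 0.083, higher). With the correction the median also turned for p53 targets (0.20 to -0.010), NRF2 targets (0.067 to -0.047), apoptosis regulators (0.041 to -0.0026), the unfolded protein response (-0.049 to 0.0070) and the protease-activated receptor list (0.036 to -0.13).

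The authors' deposited table gives 2975 genes higher and 2932 lower at an adjusted p under 0.05. Its log2 fold changes had a Spearman correlation of 0.99999 with those computed here across 12449 genes, which are not independent replicates. Of the genes called here, 5857 were called in the same direction in the authors' deposited table and 0 in the opposite direction. Both comparisons rest on the counts of the same 6 libraries, so this match was set in advance. It checks the direction of the fold changes and is no independent support. For MMP1 the authors' deposited table has a log2 fold change of 0.13 (adjusted p = 0.420), and for F2R -0.22 (adjusted p = 0.0156).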

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

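The GC and length correction and its combinations were chosen after seeing the data; the other settings were chosen before. Counts of genes higher and lower stayed within 1.5 times under the settings run, except that 120 genes were higher by at least 2-fold with the correction and 125 with the replicate block and the correction, against 363, since the correction takes out the part of a fold that follows GC and length. Leaving out 1 library gave 2503 to 3234 genes higher and 2608 to 3375 lower. MMP1 stayed short of the threshold with a positive fold change under the settings run. F2R stayed lower but lost its call with library totals only (log2 fold change -0.15), at a threshold of 0.01 (-0.23), with the correction (-0.10) and with the block and the correction (-0.10). Without single libraries F2R was at -0.27 to -0.16, short of the threshold without control 2, control 3, exosome 1 or exosome 2, for a cause that was not tested.

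The correction turned BSG to -0.089, ISG15 to -0.16, CYC1 to -0.048, HIST1H1C to -0.23 and TGFB1 to -0.22, and with the block added these were -0.088, -0.16, -0.045, -0.23 and -0.22. Without single libraries PECAM1 was at -0.47 to 0.0022, above 0 without control 1, and ROBO4 at -0.37 to 0.48, above 0 without control 3 or exosome 3 (0.22); the cause was not tested.

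Of the lists, 5 were higher and 6 lower. With an estimated correlation these were 0 and 0, with the correction as well 0 and 0, and by fry 14 and 13. With the correction 7 were higher and 11 lower, and with the block and the correction 6 and 11, the senescence-associated list being short of the threshold there. Without single libraries 4 to 7 lists were higher and 5 to 8 lower.

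Both groups' titles share the numbers 1 to 3. Deviations of same-numbered libraries from their group means correlated at 0.0664, 0.103 and 0.206 across genes. One of these is under 0.1, so the numbers were not taken as pairing, although all 6 libraries correlated best with their own number, a hint from the data and not the design. GC slopes also fell from library 1 to 3 in both groups (-0.107, -0.128 and -0.177 in control, 0.215, 0.139 and 0.0564 with exosomes). The replicate block gave 3444 genes higher and 3525 lower and changed no call of a named gene or list. Depth limits the low genes: SFTPB had 3 to 8 reads per control library.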

Other observations

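The GC and length correction and the tests of a GC difference between libraries and of carried-over fibroblast RNA were chosen only after the results were seen.

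Several markers of other cell types, picked here after their counts were seen, were near the limit of detection. The leukocyte marker PTPRC had 0 to 4 reads per library, and the fibroblast markers PDGFRA, THY1 and FAP had 0 to 3. The fibroblast collagen COL3A1 had 4, 5 and 1 reads in the control libraries and 0, 0 and 3 in the exosome libraries.

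Fold changes rose with transcript GC content (Spearman 0.617 across genes). The widest range of GC slopes within a group, whose libraries had the same treatment, was 0.159 log2 units per 10 percentage points, or 0.579 of the gap of 0.274 between the group means. This is consistent with a GC-dependent difference from preparation or sequencing that adds to the trend or makes it up. The exosome slopes (0.0564 to 0.215) all lie above the control slopes (-0.177 to -0.107) and no label gives a preparation batch, so an effect of the exosomes on GC-rich transcripts stays open and untested. Slopes fell from library 1 to 3 in both groups, so the range within a group may follow the replicate number. Of 6434 calls, 3359 ended with the trend removed.

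Of the 10 largest rises and 10 largest falls, 20 stayed past the threshold in the same direction with the trend removed. They were picked for the largest folds, while the median log2 fold change of the GC bins ran only from -0.39 to 0.49. Removing a trend of that size could hardly end such calls, so this count does not weigh on their cause. It shows only that the trend was smaller than these folds. Whether fibroblast RNA carried over with the exosomes adds to the rises stays open: the summed level of 5 fibroblast markers that these cells hardly express (COL3A1, PDGFRA, THY1, FAP and SFRP1) was 0.525 ± 0.281 CPM in control and 0.405 ± 0.159 CPM with exosomes (mean ± SD, n = 3), a difference of -0.120 CPM. These 5 were the fibroblast markers below the filter on low counts, so a marker raised past the filter would have left the sum. No library here holds the RNA of the fibroblasts or their exosomes, so the level that carried-over RNA would give these 5 markers is unknown. A hypothesis left open is that exosomes changed the expression of these 20 genes, which may include effects of culture density, a measure the labels do not give.

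Among 10000 random lists matched on GC, length and expression, which ignore correlation between genes, TGF-beta targets and YAP-TEAD targets lay at percentile 0, ribosomal proteins at 100 and nuclear oxidative phosphorylation genes at 98.29. With the trend removed all 4 lists stayed past the threshold at camera's preset correlation, which argues against the trend as fitted being their whole cause. None passed with an estimated correlation (adjusted p = 0.0611, 0.0990, 0.195 and 0.197, in that order). Both the correction and the matched lists used the longest annotated transcript, which need not be the one expressed. Part of the trend may thus remain in these lists. The medians went from -0.94 to -0.68 for TGF-beta targets, from -0.56 to -0.26 for YAP-TEAD targets, from 0.51 to 0.27 for ribosomal proteins and from 0.37 to 0.25 for oxidative phosphorylation, so the trend may account for part of each change. Members of the last pair of lists also move together between libraries (estimated correlations 0.476 and 0.340), while those of the first pair hardly do (0.0196 and 0.0360). Without the correction none of the 4 lists passed camera with an estimated correlation either (adjusted p = 0.166 for the first pair and 0.400 for the second pair). An effect of the exosomes on these lists and reads shared with ribosomal pseudogenes stay open and untested.

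With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 6434 genes and the highest other 0 in edgeR's test, where the other splits had up to 263 genes at an unadjusted p under 0.05 and 0 with DESeq2. Each other split mixes both groups on both sides, so the group difference adds to its spread. Their low counts were thus largely set in advance and decide nothing.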
